A study of Homo sapiens with 64 samples.

How the data were processed

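The series holds 64 arrays of BEAS-2B cells, 4 replicates in each of 16 groups (4 treatments at 4 times). Per the labels' protocols, cells were grown in serum-free keratinocyte medium, treated at confluence with vehicle, 10 nM indacaterol, 10 nM GSK256066 (GSK) or both, and their RNA was extracted with the RNeasy protocol and turned into biotinylated cRNA with a 3' in vitro transcription kit. The deposited values are probe-set intensities made by the authors. PLIER and Transcriptome Analysis Console 4 are named per the submitters' processing notes, with no order, background method or settings stated. The intensities as deposited are linear, never negative, and were scaled between arrays: the lower quartile per array ran from 34.12 to 42.31, the median from 101.2 to 127.4 and the upper quartile from 441.4 to 603.7, so the arrays were close but not quantile normalized after summarization. The highest signal of an array lay between 16840 and 18910 in replicates 1, 2 and 4 and between 265800 and 1082000 in replicate 3. Detection calls were not used here, so dim genes were judged only by their signal.

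Of 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 several and 11721 none in the platform annotation, and 41037 took their current symbol through the gene ID. Values were used as log2(value + 16). For each of 19775 symbols the probe set with the highest mean over all arrays was tested (10523 genes had more than 1). Probe sets without a single symbol were left out and fitted apart.

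One limma model (version 3.58.1, R 4.3.3) was fitted to all 64 arrays with a mean per group, 48 residual and a median of 2.92 prior degrees of freedom, so that every comparison shared one estimate of spread. Contrasts were tested with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over genes and calls at an adjusted p under 0.05. Each treatment was compared with vehicle at its own time, both drugs with indacaterol, and both drugs minus GSK with indacaterol minus vehicle (the interaction). Moderated F-tests asked whether the indacaterol effect, or vehicle itself, differed between times. Group counts of genes changed at least 2-fold refer to the log2 scale used.

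The genes named by rule were, per comparison of 2 groups, the 5 greatest rises and 5 greatest falls among called genes whose 4 values in one group all lay above the 4 in the other (exact two-sided p = 0.0286, the smallest that 4 against 4 can give), and for interactions the 3 greatest of each sign. Members of the fixed lists and the PDE4 genes could be named whatever their values. This rule, the comparisons and their tests, the 19 gene lists and every alternative except one were set before the data were examined. The tests of explanations for replicate 3, the later response and interferon-stimulated genes at 6 h were chosen after the results were seen. The alternative set later, a fit with replicate number as a block on replicates 1, 2 and 4, was chosen after replicate 3 was seen to stand apart.

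The lists were CREB targets, cAMP pathway components, glucocorticoid-inducible genes, cytokines and chemokines, growth factors, YAP targets, ERK pathway outputs, mitotic genes, circadian clock genes, cholesterol synthesis genes, genes of the unfolded protein and amino acid responses, interferon-stimulated, hypoxia-inducible and NRF2 target genes, ion transport and mucin genes, squamous differentiation genes, and markers of fibroblasts, leukocytes, and ciliated and secretory cells. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 380 tests (19 lists in 20 comparisons), and again with an estimated correlation. Of 53 list tests called with the preset correlation, 3 held with an estimated one: CREB targets with indacaterol at 1 and 2 h and with both drugs at 2 h. With replicate number as a block as well 10 did, these 3, CREB targets with both drugs at 1 h, and glucocorticoid-inducible genes with indacaterol and with both drugs at 1, 2 and 6 h. By the rule given in the next paragraph, the numbers were not taken to pair the samples for indacaterol at 2 h or both drugs at 1 h. Members are also counted adjusted over the list alone. Several lists share members, such as DUSP1 and RGS2 in the CREB and glucocorticoid-inducible lists.

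Replicate numbers recur in every group, and nothing in the labels says what they mark. They were taken to pair the arrays of a comparison where the deviations of same-numbered arrays from their group means correlated above 0.1 for all 4 numbers, which was decided before calls were compared. This held for 12 of 16 comparisons of 2 groups and for the interactions at 6 and 18 h. It did not hold for indacaterol at 2 h (lowest r 0.0802), GSK at 2 h (-0.0527), both drugs at 1 h (0.0804), both drugs against indacaterol at 1 h (0.0845), or the interactions at 1 and 2 h. Statements that the numbers do or do not pair the samples refer to this rule alone. It turns on the lowest of the 4 correlations, and another measure gave another picture. Treated arrays correlated best with the vehicle array of their own number in 4 of 4 cases for indacaterol at 2 h and both drugs at 1 h, which failed the rule. They did so in 2 of 4 for GSK at 6 h and both drugs at 2 h, which passed it. The rule also depends on replicate 3: without it the lowest r was 0.11 for indacaterol at 2 h. It was -0.0279 for GSK at 6 h, 0.0494 for both drugs at 2 h and -0.0071 for both drugs against indacaterol at 2 h.

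Overlaps between comparisons that share vehicle arrays were set against independent lists, against 20 simulations of unchanged groups and against splits of the vehicle arrays. The alternatives were the replicate block, eBayes with trend and robust settings, only a comparison's own arrays, dim genes left out, all named probe sets, quantile normalization, log2(value + 1), and leaving out single arrays or a replicate number, and lists were also tested with limma's fry. The model was tested on simulated data shaped like the comparison of indacaterol with vehicle at 2 h, over 19775 genes with a replicate effect. Without a block it recovered 53.8% of 1.5-fold, 90% of 2-fold and 100% of 4-fold changes with 1 false call, and with a block 73.8%, 97.5% and 100% with 11 false calls. On data simulated without a replicate effect the fit without a block recovered 63.7%, 93.8% and 100% with 9 false calls. Each setting was 1 draw. The simulated replicate effect was the same in every group, which favours the block.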

Results

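Gene expression was measured on 64 arrays in BEAS-2B cells, an immortalised human airway epithelial line, as 16 groups of 4 replicates. Confluent cells received vehicle, 10 nM indacaterol, 10 nM GSK256066 (GSK in the labels) or both drugs for 1, 2, 6 or 18 h. Indacaterol is a long-acting bronchodilator that raises cyclic AMP (cAMP) through adenylyl cyclase. GSK is an inhibitor of phosphodiesterase 4 (PDE4), an enzyme family that breaks cAMP down. The design asks what each drug does to gene expression at each time and whether the pair does more than indacaterol. Median signal per array ran from 101.2 to 127.4 and 19775 genes were tested. If no gene changed, a share of 0.05 of them would on average have an unadjusted p under 0.05. Nothing in the labels says that the replicates were separate cultures, so each p-value measures the spread between these samples, and 4 arrays per group limit the precision. Log2 changes are on the log2(signal + 16) scale, which understates the change of low genes, and stand with their SE at n = 4 per group.

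**Figure D1:**
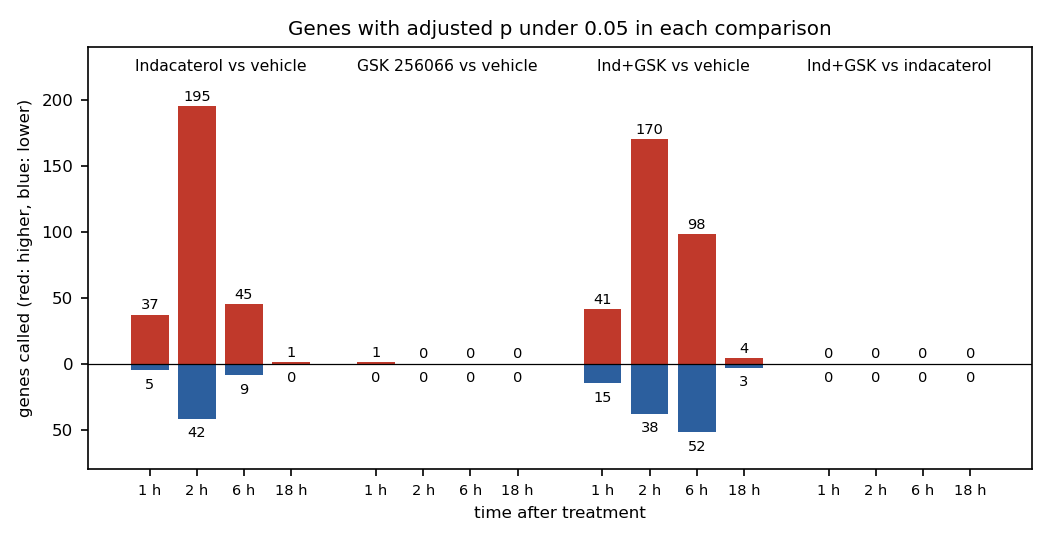
Number of genes called at an adjusted p under 0.05 (vertical axis) in 16 comparisons of 4 arrays with 4 arrays, by time after treatment in hours (horizontal axis). Red bars above 0 count genes that were higher and blue bars below 0 genes that were lower; the bars for indacaterol peak at 2 h with 195 and 42, and those for both drugs against indacaterol are at 0.

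The 16 arrays of replicate 3, which span every treatment and time, stood apart from the other 48. In them 87 genes were at least 4-fold higher and 3 at least 4-fold lower with no overlap, against 0 such genes for replicates 1, 2 and 4. On the log2(signal + 16) scale, which understates genes dim elsewhere, the 4 genes with the greatest differences were KRT14, S100A9, KRT5 and KRT19. KRT14 had a mean signal of 331000 in replicate 3 and 24.0 elsewhere, and KRT5 32700 and 165. S100A9 ran from 96850 to 1082000 there, against at most 192.7 elsewhere, and S100A8 from 818.9 to 8698, against at most 62.71. Within replicate 3 both differed between treatments, with 1 array each and no test. At 18 h S100A9 had 96850 with vehicle, 109100 with GSK, 544800 with indacaterol and 1082000 with both drugs, and S100A8 had 818.9, 999.2, 4591 and 8698. The 3 lower genes were ALPP, a placental alkaline phosphatase (64.1 and 943), UBE2QL1 (83.8 and 421) and the growth factor family member FGF13 (160 and 746). Replicate 1 lay between replicate 3 and the others for ALPP (261.9 to 543.1, against 643.2 to 1694 in replicates 2 and 4) and FGF13 (309.7 to 426.9, against 770.3 to 1100). For BCHE (butyrylcholinesterase) replicates 1 and 3 were both low, at 205.6 to 430.8 and 123.8 to 248.2, against 2984 to 5307 in replicates 2 and 4. The same held for PCDH17, a protocadherin (121.9 to 243.3 and 56.42 to 162.9, against 1106 to 2301). These genes were singled out after their values were seen. Among the fixed lists, 3 of the 23 squamous differentiation genes (KRT16, S100A8 and S100A9) and 4 of the 25 ion transport and mucin genes (SCNN1A, KCNN4, AQP3 and CA2) were higher on all 16 of these arrays than on any other, and the squamous differentiation gene CNFN was lower on all of them. The medians over both lists differed by 0.028 and 0.051.

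**Figure D2:**
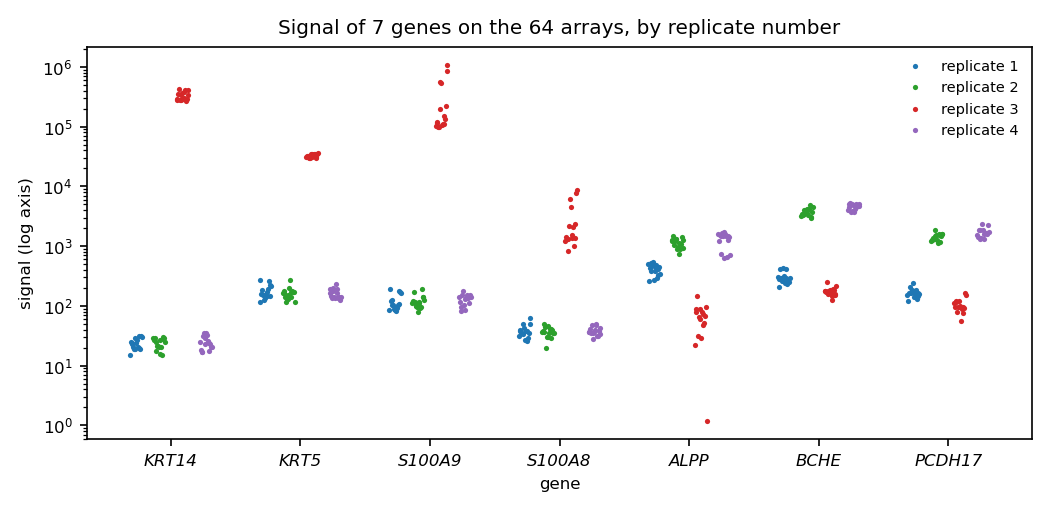
Signal (vertical axis, log scale) of 7 genes on the 64 arrays, 1 point per array, coloured by replicate number. The 16 arrays of replicate 3 lie above all others for KRT14, KRT5, S100A9 and S100A8 and below all others for ALPP. For BCHE and PCDH17 the arrays of replicates 1 and 3 overlap and lie below those of replicates 2 and 4.

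After 1 h of indacaterol the greatest changes were rises. NR4A2 and NR4A3, orphan nuclear receptors of the immediate early class, rose by 4.21 ± 0.75 (adjusted p = 0.000764) and 3.88 ± 0.58 (adjusted p = 3.41e-05). IL6, an inflammatory cytokine, rose by 3.32 ± 0.47, from a signal of 161 to 1876. PRDM1, a transcriptional repressor, rose by 2.56 ± 0.28 (adjusted p = 1.36e-08), and SIK1, a salt-inducible kinase that restrains CREB signalling, rose by 2.33 ± 0.39. The greatest falls were far smaller: MIR181A2HG, a microRNA host transcript, fell by 0.81 ± 0.18, and ZNF57, ZNHIT2, SERTAD3 and C1orf74 fell by 0.47, 0.42, 0.39 and 0.36. Without replicate 3 the calls of these 5 falls were lost, with adjusted p from 0.14 for ZNF57 to 0.498 for MIR181A2HG, at changes of -0.57, -0.42, -0.39, -0.34 and -0.32 in the order given. The other probe sets of ZNHIT2 gave -0.38 and, at a dim signal, 0.42.

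Of 23 measured targets of CREB, the transcription factor that protein kinase A activates, 6 rose after 1 h of indacaterol (NR4A1, NR4A2, NR4A3, SIK1, RGS2 and DUSP1) and 0 fell, while 9 rose and 1 fell when adjusted over the list alone. The list as a whole shifted up (limma camera, adjusted p = 5.62e-18 with the preset inter-gene correlation, and adjusted p = 0.0328 with an estimated correlation). Of 22 glucocorticoid-inducible genes, DUSP1, RGS2 and SGK1 rose (4 adjusted over the list alone), at an adjusted p of 1.22e-09 and an adjusted p of 0.237 with an estimated correlation (0.0131 with the block as well). SGK1, a kinase that regulates ion transport, rose by 2.20 ± 0.23 (adjusted p = 2.39e-09). Of 31 cytokines and chemokines, IL6, CXCL2 and CCL20 rose (5 rose and 1 fell adjusted over the list alone), with adjusted p = 4.9e-05 for the list and adjusted p = 0.0936 with an estimated correlation. The chemokine genes CXCL2 and CCL20 rose by 2.18 ± 0.40 and 1.73 ± 0.33. EDN1, the gene of the vasoconstrictor peptide endothelin-1, rose by 1.77 ± 0.18, the only call among 22 growth factors (2 rose adjusted over the list alone, adjusted p = 0.0548 for the list, 0.000166 with replicate number as a block, and adjusted p = 0.281 with the block and an estimated correlation).

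In total limma called 42 genes at 1 h, 37 higher and 5 lower, of which 18 rose at least 2-fold and 0 fell at least 2-fold (1399 genes had an unadjusted p under 0.05). With replicate number as a block the count was 206. Without replicate 3 of the indacaterol group at 1 h it was 27.

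After 2 h of indacaterol the response was at its broadest. NR4A3 rose by 5.58 ± 0.58, from a signal of 27.1 to 2171 (adjusted p = 1.81e-09), and NR4A2 rose by 4.27 ± 0.75. LINC00473, a long non-coding RNA known to respond to cAMP, rose by 3.47 ± 0.33 (adjusted p = 1.82e-10). CRISPLD2, a secreted protein that binds lipopolysaccharide, rose by 2.94 ± 0.37 (adjusted p = 2.58e-07) and IL6 rose by 2.77 ± 0.47. The other probe set of CRISPLD2 gave -0.13 at 2 h and -0.19 at 6 h, neither called. EGR1, an immediate early transcription factor, fell by 1.40 ± 0.19 (adjusted p = 1.3e-06), and TXNIP, an inhibitor of thioredoxin, fell by 1.20 ± 0.21. CCNF (cyclin F) and BORA, an activator of the mitotic kinase Aurora A, fell by 0.85 ± 0.16 and 0.81 ± 0.12, and KLF7 fell by 0.75 ± 0.16.

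The CREB list was again shifted up at 2 h (adjusted p = 6.94e-23, and adjusted p = 0.00948 with an estimated correlation): 11 of its 23 members rose and EGR1 fell (12 and 1 adjusted over the list alone). The 11 included the repressor CREM, the neurotrophin BDNF, up by 1.98 ± 0.37, and the phosphodiesterases PDE4B and PDE4D. Of the glucocorticoid-inducible genes 5 rose, CRISPLD2 and CEBPD joining DUSP1, RGS2 and SGK1 (7 adjusted over the list alone; adjusted p = 5.45e-14, adjusted p = 0.104 with an estimated correlation, and 0.00268 with the block as well). Among cytokines, IL6, CXCL2, CCL20 and IL15 rose (5 adjusted over the list alone), with adjusted p = 0.00193, and adjusted p = 0.237 with an estimated correlation. Of 45 cAMP pathway components, PDE4B, PDE4D, SIK1 and SIK2 rose (6 adjusted over the list alone), with adjusted p = 0.00106, and adjusted p = 0.0936 with an estimated correlation.

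The growth factors VEGFC and EDN1 rose at 2 h (2 rose and 1 fell adjusted over the list alone, adjusted p = 0.0217, and adjusted p = 0.231 with an estimated correlation). So did 3 of 21 YAP targets: CCN2, IGFBP3 and FJX1 (4 adjusted over the list alone, adjusted p = 0.00531, and adjusted p = 0.987 with an estimated correlation). CCN2, a matricellular protein, rose by 1.31 ± 0.28. Of 34 mitotic genes, CDCA8, a chromosomal passenger protein, fell by 0.56 ± 0.11 and 33 did not pass the test (2 fell adjusted over the list alone), while the list shifted down by a median of -0.16 (adjusted p = 2.13e-07, and adjusted p = 0.43 with an estimated correlation). It also lay lower at 1 h, by a median of -0.078 with 0 members called (adjusted p = 0.0394, and adjusted p = 0.987 with an estimated correlation). At 2 h limma called 237 genes, 195 higher and 42 lower, with 63 and 2 of them changed at least 2-fold (1584 genes had an unadjusted p under 0.05). Without replicate 3 the calls of CREM (adjusted p = 0.105), FOSB (adjusted p = 0.146) and CDCA8 (adjusted p = 0.0534) were lost, at changes of 0.45, 0.87 and -0.48. Quantile normalization of the arrays gave 204 higher and 132 lower, so the share of falls among the calls depends on the scaling.

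**Figure D3:**
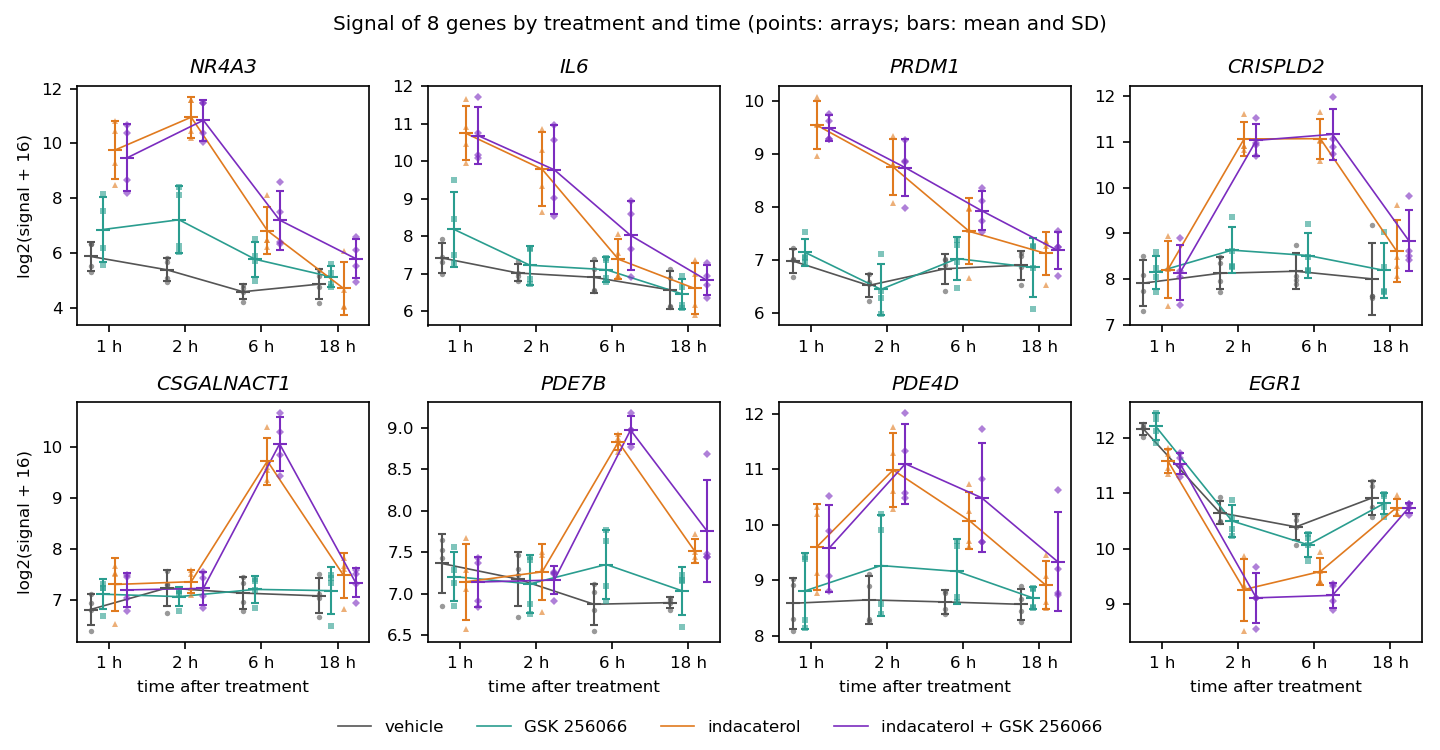
Log2(signal + 16) (vertical axis) of 8 genes by time after treatment in hours (horizontal axis) and treatment. Each point is an array, each bar the mean and SD of 4 arrays. NR4A3, IL6 and PRDM1 with indacaterol peaked at 1 or 2 h, CSGALNACT1 and PDE7B stood high at 6 h, and EGR1 lay below vehicle at 2 and 6 h.

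After 6 h of indacaterol CRISPLD2 was 2.89 ± 0.37 above vehicle (adjusted p = 1.06e-06). CSGALNACT1, an enzyme that starts chondroitin sulfate chains, rose by 2.58 ± 0.25 (adjusted p = 1.33e-09, other probe set 0.033), and PDE7B, a cAMP-specific phosphodiesterase, rose by 1.95 ± 0.22 (adjusted p = 5.38e-08). LINC00473 rose by 1.99 ± 0.33 and STEAP4, a metalloreductase, rose by 1.82 ± 0.30. EGR1 fell by 0.81 ± 0.19, TMT1B, a thiol methyltransferase, fell by 0.57, C1orf198 fell by 0.53, and the phosphate transporter SLC20A2 fell by 0.49. Without replicate 3 the calls of EGR1 (adjusted p = 0.302), TMT1B (adjusted p = 0.145), SLC20A2 (adjusted p = 0.115) and LSS (adjusted p = 0.111) were lost, at changes of -0.75, -0.59, -0.44 and -0.48. The other probe sets of SLC20A2 gave 0.10 and -0.23.

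Cholesterol synthesis genes were lower after 6 h of indacaterol: of 18 measured, the sterol enzymes LSS and MVK fell by 0.50 ± 0.12 and 0.48 ± 0.083, and 6 fell when adjusted over the list alone. The median over the list was -0.18 (adjusted p = 1.08e-11, and adjusted p = 0.144 with an estimated correlation). The CREB list was up with adjusted p = 0.000609 and adjusted p = 0.709 with an estimated correlation. In the fit without a block 0 of its members rose and EGR1 fell over all genes (4 rose and 1 fell adjusted over the list alone). Its member PDE4D, 1.47 above vehicle, was among the genes called with the block (limma, adjusted p = 1.05e-06). The glucocorticoid-inducible list was up (adjusted p = 1.07e-07, adjusted p = 0.371 with an estimated correlation, and 0.0376 with the block as well), with CRISPLD2 called over all genes and 5 adjusted over the list alone. PDE7B was the 1 cAMP pathway component called (2 adjusted over the list alone; adjusted p = 0.0726 for the list, 0.0178 with the block, and adjusted p = 0.803 with the block and an estimated correlation), and IGFBP3 rose among YAP targets. At 6 h limma called 54 genes, 45 higher and 9 lower, and 15 rose at least 2-fold. The count was 457 with replicate number as a block and 97 without replicate 3.

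After 18 h of indacaterol 1 gene passed: FSD2 rose by 0.59 ± 0.11 at low signal, from 35.2 to 61.1 (limma, adjusted p = 0.0429), while 875 genes had an unadjusted p under 0.05. These 875 are fewer than unchanged genes would give on average. YAP targets and interferon-stimulated genes lay lower, with medians of -0.10 (adjusted p = 0.0172) and -0.20 (adjusted p = 0.0394) and 0 members called in either, and each list had adjusted p = 0.987 with an estimated correlation, and 0.364 and 0.0536 without replicate 3. With the block 7 genes were called, and without replicate 3 the count was 0, as it was when vehicle replicate 1, 2 or 3 or indacaterol replicate 2, 3 or 4 at 18 h was left out singly; without vehicle replicate 4 it was 4.

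The size of the indacaterol effect differed between times for 53 genes (limma moderated F-test over 1, 2, 6 and 18 h; 851 genes at an unadjusted p under 0.05). The count was 394 with the block, 87 with quantile normalization, and 25, 8 and 27 without replicate 1, 2 or 4. The 851 genes at an unadjusted p under 0.05 are fewer than unchanged genes would give on average. For SGK1 (adjusted p = 5.67e-07) and EDN1 (adjusted p = 6.46e-06) the effect at 18 h was below that at 1 h by -2.18 and -1.69. For CSGALNACT1 and PDE7B the effect at 6 h was above that at 1 h by 2.09 and 2.17. The effect on NR4A3 was 1.69 greater at 2 h than at 1 h and then smaller by -1.65 at 6 h and -4.04 at 18 h (adjusted p = 0.000118), and that on PRDM1 was smaller by -1.85 at 6 h.

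Of the PDE4 genes, PDE4A, PDE4B and PDE4D had a named probe set and PDE4C was not analysed here. PDE4D rose by 2.34 ± 0.44 with indacaterol at 2 h, from a signal of 398 to 2188 (adjusted p = 0.000665), and by 2.46 ± 0.44 with both drugs (adjusted p = 0.000336). PDE4B rose by 0.99 ± 0.23 (adjusted p = 0.00741) and 0.96 ± 0.23 (adjusted p = 0.0125). At 6 h PDE4D was 1.47 ± 0.44 above vehicle with indacaterol (adjusted p = 0.242, and 1.05e-06 with the block). With both drugs it rose by 1.88 ± 0.44 (adjusted p = 0.0165, 1.18e-09 with the block, and 0.0604 without replicate 3, at a change of 1.52). At 1 h indacaterol gave PDE4D a difference of 1.02 ± 0.44 (adjusted p = 0.579, and 0.00171 with the block) and PDE4B one of 0.80 ± 0.23 (adjusted p = 0.165, and 0.0135 with the block). GSK gave PDE4D 0.22, 0.62, 0.55 and 0.11 at 1, 2, 6 and 18 h, none of them called with or without the block. PDE4A was not called, and its brightest probe set gave values from -0.10 to 0.12 against vehicle, while the next brightest gave up to 0.36 (GSK at 1 h) and a dim one up to 0.66, none of them called. Among the 5 other probe sets of PDE4D, 3 rose with indacaterol at 2 h, by 1.92, 1.98 and 2.31, and the remaining ones gave 0.050 and -0.13. With both drugs the same 3 rose by 1.86, 1.96 and 2.31 and the remaining ones gave 0.075 and -0.058. Another bright probe set of PDE4B gave 0.84 (adjusted p = 0.0503) and 0.81 (adjusted p = 0.077), and a dim one 0.20 and -0.054.

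GSK alone gave 1 call against vehicle among the 19775 genes. CYP2E1, a cytochrome P450, rose by 0.54 ± 0.097 at 1 h at low signal, from 44.2 to 71.2 (limma, adjusted p = 0.0209). Limma called 0 genes at 2, 6 and 18 h, where 899, 346 and 704 genes had an unadjusted p under 0.05, and 1404 did at 1 h. Unchanged genes would on average give more than the counts at 2, 6 and 18 h, and fewer than that at 1 h. The genes that responded most to indacaterol gave positive values that did not pass: NR4A3 was 0.98 (95% interval -0.18 to 2.14) above vehicle at 1 h, 1.83 (0.67 to 2.99) at 2 h and 1.18 (0.023 to 2.35) at 6 h, with adjusted p = 0.752 at 2 h. NR4A2 was 1.60 (0.099 to 3.10) above it at 1 h, LINC00473 0.67 (0.015 to 1.33) at 2 h and PDE7B 0.48 (0.033 to 0.92) at 6 h. Of the genes named at 18 h, FSD2 (0.53, 0.30 to 0.75), MMP20 (0.47, 0.11 to 0.82) and P4HTM (0.15, 0.027 to 0.26) also had intervals above 0. Intervals below 0 were those of ZNF57, CDC42EP1 and C1orf74 at 1 h (-0.26, -0.24 and -0.20) and C1QTNF2 at 6 h (-0.38). All of these genes were named in comparisons with the same vehicle arrays. Low or high vehicle values alone can therefore move these intervals from 0, and they are not independent signs of a GSK effect. A p that misses the threshold does not show that GSK left these genes as they were. The CYP2E1 call was lost without replicate 3 in all groups (adjusted p = 0.346, at a change of 0.52), without vehicle replicate 1 or 3 or without GSK replicate 2, 3 or 4 at 1 h, and 12 genes were called without GSK replicate 1. At the later times 1 gene was called without vehicle replicate 4 (2, 6 and 18 h) or without GSK replicate 3 (2 h), against 0 with all arrays.

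Some lists shifted with GSK although 0 of their members were called. CREB targets (adjusted p = 0.000879, mean 0.20) and glucocorticoid-inducible genes (adjusted p = 0.0349, mean 0.054) lay higher at 2 h, with adjusted p = 0.728 and adjusted p = 0.987 with an estimated correlation. These are means, which a few members can carry. Among the CREB targets NR4A3 was 1.83, NR4A2 1.06, PDE4D 0.62 and PDE4B 0.26 above vehicle, and EGR1 differed by -0.15. Interferon-stimulated genes lay lower at 6 h by a median of -0.29 (adjusted p = 9.9e-07, and adjusted p = 0.872 with an estimated correlation). Over this list vehicle arrays at 6 h stood 0.385 above vehicle at the other times, and treated arrays differed by -0.00177 over the 3 treatments together (-0.37 to 0.591 in single groups and replicates). The 18 leukocyte markers lay higher at 1 h by a median of 0.11 (adjusted p = 0.0252, and adjusted p = 0.371 with an estimated correlation). With replicate number as a block, 5 further list tests passed: CREB targets up at 1 h (adjusted p = 0.186, and 0.0137 with the block), interferon-stimulated genes up at 2 h (0.111, and 0.0382 with the block, where the numbers do not pair the samples), glucocorticoid-inducible genes up at 6 h (0.25, and 0.00551 with the block), cholesterol synthesis genes down at 6 h (0.0769, and 0.0182 with the block) and interferon-stimulated genes up at 18 h (0.0563, and 6.83e-05 with the block). With an estimated correlation beside the block each of the 5 had an adjusted p of at least 0.843.

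With both drugs together for 1 h, NR4A2 rose by 4.18 ± 0.75, IL6 by 3.26 ± 0.47 (adjusted p = 1.82e-05) and SIK1 by 2.27 ± 0.39, and NR4A3 (adjusted p = 0.000152) and PRDM1 (adjusted p = 2.79e-08) rose as well, with signals of 893.2 and 705.5 against 45.3 and 111.2. ZNF57 fell by 0.57, SERTAD3 by 0.51, METTL18, a histidine methyltransferase, by 0.47, CDC42EP1, an effector of the GTPase CDC42, by 0.41 and THAP3 by 0.39. Without replicate 3 the calls of METTL18 (adjusted p = 0.0706) and CDC42EP1 (adjusted p = 0.0931) were lost, at changes of -0.47 and -0.46. CREB targets again shifted up, with 6 members called (9 rose and 1 fell adjusted over the list alone; adjusted p = 1.54e-14, adjusted p = 0.0619 with an estimated correlation, and 0.00084 with the block as well). DUSP1, RGS2 and SGK1 rose among glucocorticoid-inducible genes (6 adjusted over the list alone; adjusted p = 2.47e-08, adjusted p = 0.328 with an estimated correlation, and 0.0385 with the block as well), and IL6, CXCL2 and CCL20 among cytokines (5 adjusted over the list alone; adjusted p = 2.2e-05, and adjusted p = 0.0926 with an estimated correlation). Leukocyte markers lay higher with 0 called (adjusted p = 0.0172, and adjusted p = 0.331 with an estimated correlation). Limma called 56 genes, 41 higher and 15 lower, with 18 up at least 2-fold. The count was 34, 32 and 33 without vehicle replicate 1, vehicle replicate 2 or replicate 3 of both drugs at 1 h, and 87 without vehicle replicate 4.

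Both drugs together for 2 h raised NR4A3 by 5.46 ± 0.58 (adjusted p = 3.61e-09), NR4A2 by 4.22 ± 0.75, LINC00473 by 3.35 ± 0.33 (adjusted p = 6.12e-10), CRISPLD2 by 2.90 ± 0.37 and IL6 by 2.75 ± 0.47. EGR1 fell by 1.55 ± 0.19, TXNIP by 1.42 ± 0.21, BORA by 0.90 ± 0.12, CCNF by 0.83 ± 0.16 and HJURP, a chaperone of centromeric histone, by 0.70 ± 0.13. Of the CREB targets 11 rose and EGR1 fell (12 and 1 adjusted over the list alone; adjusted p = 3.46e-26, and adjusted p = 0.00631 with an estimated correlation). In addition 5 glucocorticoid-inducible genes rose (7 adjusted over the list alone; adjusted p = 1.43e-17, adjusted p = 0.0619 with an estimated correlation, and 0.00084 with the block as well). PDE4B, PDE4D, SIK1 and SIK2 rose among cAMP components (6 adjusted over the list alone, adjusted p = 0.000183, and adjusted p = 0.0619 with an estimated correlation) and IL6, CXCL2, CCL20 and IL15 among cytokines (5 adjusted over the list alone, adjusted p = 0.000304, and adjusted p = 0.144 with an estimated correlation).

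Among the other lists at 2 h with both drugs, VEGFC and EDN1 rose (2 rose and 1 fell adjusted over the list alone, adjusted p = 0.00824, and adjusted p = 0.144 with an estimated correlation). So did the YAP targets CCN2, IGFBP3, FJX1 and PTPN14 (4 adjusted over the list alone, adjusted p = 0.000609, and adjusted p = 0.899 with an estimated correlation). PFKFB3, a regulator of glycolysis, rose by 0.66 ± 0.17 among 19 hypoxia-inducible genes (2 adjusted over the list alone, adjusted p = 0.0292, and adjusted p = 0.859 with an estimated correlation). The mitotic list lay lower by a median of -0.17, with CDCA8 called (3 fell adjusted over the list alone, adjusted p = 4.88e-08, and adjusted p = 0.371 with an estimated correlation). Limma called 208 genes, 170 higher and 38 lower, with 59 up and 2 down at least 2-fold. Quantile normalization gave 201 and 121, and the fit with replicate number as a block called 683 genes.

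Both drugs together for 6 h raised CRISPLD2 by 2.99 ± 0.37 and CSGALNACT1 by 2.91 ± 0.25 (adjusted p = 1.72e-11, other probe set 0.048). NR4A3 rose by 2.62 ± 0.58 (adjusted p = 0.00889) from a low signal of 8.20 to 166.7, a change that depends on the offset (3.96 with log2(value + 1)). LINC00473 rose by 2.34 ± 0.33 and SMOC1, a secreted calcium-binding matrix protein, by 2.37 ± 0.60 (adjusted p = 0.0382). PDE7B rose by 2.10 ± 0.22 (adjusted p = 5.48e-09). EGR1 fell by 1.24 ± 0.19, RBM12, an RNA-binding protein, by 0.73 ± 0.15, C1orf198 by 0.68, MVD, a mevalonate pathway enzyme, by 0.68 ± 0.13, and C1QTNF2 by 0.67. Without replicate 3 the calls of NR4A3 (adjusted p = 0.0702), SMOC1 (adjusted p = 0.137) and C1QTNF2 (adjusted p = 0.371) were lost, at changes of 2.6, 2.33 and -0.51. Of 18 cholesterol synthesis genes, LSS, MVD, MVK, NSDHL and HSD17B7 fell (7 adjusted over the list alone) and the list had a median of -0.24 (adjusted p = 7.56e-14, and adjusted p = 0.0936 with an estimated correlation). The CREB targets NR4A3, SIK1, PDE4D, RGS2 and DUSP1 rose and EGR1 fell (7 rose and 1 fell adjusted over the list alone, adjusted p = 1.99e-07, and adjusted p = 0.289 with an estimated correlation). DUSP1, CRISPLD2, RGS2, SGK1 and CEBPD rose among glucocorticoid-inducible genes (7 adjusted over the list alone, adjusted p = 1.4e-10, adjusted p = 0.225 with an estimated correlation, and 0.0137 with the block as well).

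The cAMP components PDE4D, PDE7B and SIK1 rose after 6 h of both drugs (6 adjusted over the list alone, adjusted p = 0.00451, and adjusted p = 0.144 with an estimated correlation). Mitotic genes lay lower with 0 called (5 fell adjusted over the list alone, adjusted p = 5.17e-05, and adjusted p = 0.709 with an estimated correlation), as did interferon-stimulated genes with 0 called (adjusted p = 0.0214, and adjusted p = 0.987 with an estimated correlation), where vehicle arrays stood high by 0.385. Limma called 150 genes, 98 higher and 52 lower, with 30 up and 1 down at least 2-fold. Quantile normalization gave 165 higher and 164 lower and the block gave 1043 calls, 505 higher and 538 lower, so the balance of rises and falls was not settled. The count was 94 and 83 without replicate 1 or 3 of both drugs at 6 h.

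After 18 h of both drugs 7 genes passed. CLIC5, a chloride intracellular channel protein, fell by 1.02 ± 0.20 (adjusted p = 0.0147), TNS1 (tensin 1, of focal adhesions) by 0.57 ± 0.095 (adjusted p = 0.002) and TMEM158 by 0.51 ± 0.093. P4HTM, a transmembrane prolyl hydroxylase, rose by 0.36 ± 0.059, DDRGK1 by 0.28 ± 0.055, FSD2 by 0.57 ± 0.11 and MMP20, a metalloproteinase, by 0.86 ± 0.18 from a low signal of 3.89 to 20.5, a change that depends on the offset (2.37 with log2(value + 1)). Interferon-stimulated genes (median -0.37, adjusted p = 1.21e-05), growth factors (-0.12, adjusted p = 0.0477, and 0.0703 with the block) and YAP targets (-0.10, adjusted p = 0.0217) lay lower with 0 members called, and had adjusted p = 0.932, adjusted p = 0.328 and adjusted p = 0.987 with an estimated correlation. With the block 80 genes were called, and CREB targets (adjusted p = 0.216, and 0.00746 with the block) and glucocorticoid-inducible genes (0.389, and 0.00924 with the block) lay higher, at an adjusted p of 0.88 each with an estimated correlation beside the block. Of the 7 calls 0 held without replicate 3, where 1 other gene was called. The changes there were -0.80 for CLIC5, -0.52 for TNS1, -0.34 for TMEM158, 0.34 for P4HTM, 0.28 for DDRGK1, 0.56 for FSD2 and 0.87 for MMP20. The 4 other probe sets of CLIC5 gave -0.41, -0.34, -0.037 and 0.064, none called. The count was 2 or 3 without vehicle replicate 1, 2 or 3 or replicate 1 or 3 of both drugs at 18 h.

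Both drugs were set against indacaterol directly to ask what GSK adds. Limma called 0 genes at 1, 2, 6 and 18 h, with and without the block, and 250, 254, 346 and 306 genes had an unadjusted p under 0.05. Each of these counts is below the share of 0.05 that unchanged genes would give on average, so they are no sign of a difference. A p that misses the threshold does not show that the treatments act alike, and the interval of a difference had a median 95% half-width of 0.28 over all genes. At 2 h NR4A3 differed by -0.12 (95% interval -1.28 to 1.05), LINC00473 by -0.12 (-0.78 to 0.54), CRISPLD2 by -0.036 (-0.77 to 0.70) and EGR1 by -0.15 (-0.53 to 0.23). At 6 h CSGALNACT1 was 0.33 (-0.18 to 0.84) higher with both drugs, LINC00473 0.35 (-0.31 to 1.01), NR4A3 0.39 (-0.78 to 1.55), PDE4D 0.41 (-0.48 to 1.30) and PDE7B 0.15 (-0.30 to 0.59), and EGR1 differed by -0.43 (-0.81 to -0.054). All intervals are from the fit without a block, though by the rule used the numbers pair the samples at 2, 6 and 18 h. For PDE4D at 6 h the SE was 0.44 without the block and 0.20 with it. At 18 h MMP20 was 0.69 (0.33 to 1.04) higher with both drugs, P4HTM 0.12 (0.0027 to 0.24) and DDRGK1 0.11 (0.00076 to 0.22), and CLIC5 differed by -0.40 (-0.79 to -0.0025), each at an adjusted p of 1. EGR1 at 6 h and these genes at 18 h were named on the same arrays of both drugs, which can bias their intervals away from 0. MMP20 was also dim, with a signal of 20.5 with both drugs at 18 h. Of the 153 genes called against vehicle at 6 h in either comparison 51 were called in both comparisons, 99 with both drugs alone and 3 with indacaterol alone, which does not show that the 99 responded differently, since 0 differed in the direct test.

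Lists differed between both drugs and indacaterol at 6 and 18 h with 0 members called. At 1 h, where the numbers do not pair the samples, interferon-stimulated genes lay lower with the block alone (0.122, and 0.00095 with the block, 0.979 with an estimated correlation beside it). At 6 h CREB targets lay higher by a median of 0.21 (adjusted p = 0.0123, and adjusted p = 0.932 with an estimated correlation), but with adjusted p = 0.517 without replicate 3. Glucocorticoid-inducible genes lay higher (median 0.084, adjusted p = 0.0349, and adjusted p = 0.987 with an estimated correlation), with adjusted p = 0.422 without replicate 3. Mitotic genes lay lower (median -0.073, adjusted p = 0.00189, and adjusted p = 0.932 with an estimated correlation). At 18 h interferon-stimulated genes (adjusted p = 0.0172) and squamous differentiation genes (adjusted p = 0.0459, 0.0939 with the block and 0.753 without replicate 3) lay lower, with adjusted p = 0.987 and adjusted p = 0.237 with an estimated correlation. With the block, cAMP components (0.182, and 0.0495 with the block), cholesterol synthesis genes, which lay lower (0.0693, and 0.0178 with the block), and interferon-stimulated genes (0.0503, and 3.81e-05 with the block) also passed at 6 h. At 18 h CREB targets (0.0761, and 0.00228 with the block) and glucocorticoid-inducible genes (0.247, and 0.0295 with the block) passed with it. Each of these 5 had an adjusted p of at least 0.803 with an estimated correlation beside the block.

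The interaction asked whether the effect of both drugs departed from the sum of the single effects on the log2 scale. Limma called 0 genes at 1, 2, 6 and 18 h, where 547, 459, 259 and 481 had an unadjusted p under 0.05, and 1, 0, 0 and 0 with the block. The counts at an unadjusted p under 0.05 are each below what unchanged genes would give on average. The value for NR4A3 at 2 h was -1.94 (95% interval -3.59 to -0.30), with an adjusted p of 1, that for NR4A2 -1.11 (-3.23 to 1.01), that for PDE4D at 6 h -0.14 (-1.39 to 1.12), and that for FSD2 at 18 h -0.55 (-0.87 to -0.24). NR4A3, NR4A2 and FSD2 were named in comparisons with the same vehicle arrays, which the interaction uses too, so these intervals are affected by that choice. CREB targets as a list lay below additivity at 2 h (median -0.14, adjusted p = 0.0127, and adjusted p = 0.932 with an estimated correlation). With the block they lay above it at 6 h (adjusted p = 0.273, and 0.0313 with the block) and at 18 h (0.186, and 0.0299 with the block), at an adjusted p of 0.979 each with an estimated correlation beside the block. At 1 and 2 h the numbers do not pair the samples. With the block CREB targets lay below additivity at 1 h (0.151, and 0.00215 with the block) and glucocorticoid-inducible genes at 2 h (0.25, and 0.0317 with the block), at 0.803 and 0.979 with an estimated correlation beside it. Interferon-stimulated genes lay above additivity at 6 h (median 0.48, adjusted p = 3.19e-08, and adjusted p = 0.713 with an estimated correlation) and below it at 18 h (median -0.33, adjusted p = 0.00128, and adjusted p = 0.987 with an estimated correlation). The interaction adds the vehicle level, and vehicle arrays at 6 h stood high over this list by 0.385. Leukocyte markers lay above it at 6 h (adjusted p = 0.0459, and adjusted p = 0.468 with an estimated correlation), and squamous differentiation genes below it at 18 h (adjusted p = 0.0394, 0.108 with the block, 0.76 without replicate 3, and adjusted p = 0.231 with an estimated correlation).

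Calls shared by indacaterol and both drugs, each against vehicle, were counted. Of 62 genes called in either at 1 h, 36 were called in both (33 higher, 3 lower), at 2 h 180 of 265 (157 and 23), at 6 h 51 of 153 (43 and 8) and at 18 h 1 of 7, with 0 in opposite directions. Independent lists of those sizes would share 0.0767 higher and 0.00379 lower genes at 1 h, 1.68 and 0.0807 at 2 h, and 0.223 and 0.0237 at 6 h. In 20 simulations of unchanged groups, with the vehicle arrays simulated too, the comparisons shared at most 0. Unchanged groups leave little to call, so this count does not show what shared vehicle arrays add to the real overlap. With the vehicle arrays split between the comparisons, which leaves 2 in each, the median overlap was 16.5, 71.5, 19.5 and 0 genes at 1, 2, 6 and 18 h. Across genes, which are not independent replicates, fold changes correlated at r = 0.835, 0.87, 0.805 and 0.734. The simulations, where the comparisons share vehicle arrays too, gave a mean of 0.5 at 1, 2 and 6 h and 0.499 at 18 h. They drew the noise of each gene independently. How far r or the covariance can move when the genes of an array deviate together is therefore not shown, also for GSK below. The covariance was 0.0275, 0.036, 0.0252 and 0.0162 against simulated values of 0.00844, 0.00842, 0.00843 and 0.00838, a difference of 0.0191, 0.0276, 0.0168 and 0.00786. With split vehicle arrays r ran from -0.104 to 0.366, 0.0396 to 0.371, -0.0939 to 0.299 and -0.295 to 0.113. At each time both splits of replicates 1 and 3 against 2 and 4 gave the lowest r, so the range follows the replicate numbers. For indacaterol and GSK the shared calls were 1 (CYP2E1 at 1 h), 0, 0 and 0, where independent lists would share 0.00187 genes at 1 h. The vehicle splits shared 0, and so did the simulations, which had little to call, for indacaterol and GSK. The covariance there exceeded the simulated one by 0.00908 at 1 h, 0.000787 at 2 h and 0.00559 at 18 h and differed by -0.000884 at 6 h, with r = 0.603, 0.327, 0.4 and 0.693 against simulated values of 0.498, 0.499, 0.501 and 0.497. With split vehicle arrays r ran from -0.314 to 0.145, -0.395 to -0.0345, -0.481 to -0.142 and -0.36 to 0.056, lowest in the same splits.

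Vehicle arrays differed between times after treatment. EGR1 was lower by -1.51, -1.77 and -1.25 at 2, 6 and 18 h than at 1 h (limma F-test, adjusted p = 5.14e-09), FOSB by -0.91, -1.79 and -1.95 (adjusted p = 5.52e-08) and NR4A1 by -0.95, -1.65 and -1.28 (adjusted p = 0.000128). CCN2 was lower by -1.27 at 6 h, and IER2, which was chosen after its values were seen, had the highest F (63.0, adjusted p = 7.34e-13). In total 1315 genes differed over time with vehicle (3798 at an unadjusted p under 0.05). The count was 4415 with the block, and 350, 414 and 774 without replicate 1, 2 or 4. Most of these changes were small: relative to 1 h, 345 were higher and 970 lower at 2 h, 459 and 856 at 6 h, and 737 and 578 at 18 h, with 1 and 2, 0 and 6, and 0 and 9 of them at least 2-fold.

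Of the fixed lists not described so far, those of ERK pathway outputs (19 genes), circadian clock genes (16), the unfolded protein and amino acid responses (22), NRF2 targets (18), ion transport and mucin genes (25), fibroblast markers (18) and ciliated and secretory cell markers (18) had 0 of 20 comparisons called by camera each. Single members did change. MYC, the phosphatase DUSP4 and the receptor kinase inhibitor SPRY2 rose among ERK outputs with indacaterol at 2 h, by 0.78 ± 0.15, 0.93 ± 0.14 and 0.85 ± 0.21, while EGR1 and EGR3 fell by 1.40 and 0.75. BHLHE40 and NFIL3, transcription factors tied to the circadian clock, rose by 1.12 ± 0.25 and 1.22 ± 0.31 at that time. HERPUD1 and DNAJB9, of the endoplasmic reticulum stress response, rose by 0.60 ± 0.098 and 0.37 ± 0.093, and ANKRD37 and PFKFB3 rose among hypoxia-inducible genes by 1.31 ± 0.36 and 0.68 ± 0.17 (adjusted p = 0.0513 for that list). TXNRD1, an NRF2 target that reduces thioredoxin, fell by 0.23 ± 0.056 with both drugs at 6 h. Interferon-stimulated genes lay higher at 1 h of indacaterol (median 0.29, adjusted p = 0.00155, and adjusted p = 0.987 with an estimated correlation) and lower at 6 h (median -0.47, adjusted p = 8.47e-07, and adjusted p = 0.87 with an estimated correlation), where vehicle arrays stood high by 0.385, with 0 of 25 called at either time.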

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

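The 3 tests of why replicate 3 stands apart were chosen only after that result was seen, and the other tests of this part were planned.

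The 16 arrays of replicate 3 differed from the other 48 in every treatment and at every time. Within the groups of 4, an array lay far outside the other 3 by Dixon's test for 342 of 1392 groups of values from the 87 genes at least 4-fold higher there, always the array of replicate 3, which follows from how the genes were chosen. Array-wide scaling is argued against, since 100% of the 87 genes stayed at least 4-fold higher after quantile normalization. If signal is proportional to RNA, so is a minority of other cells mixed in. In replicate 3 159 genes were at least 2-fold lower on the signal scale with no overlap, against 1, 0 and 1 in replicates 1, 2 and 4. An exchange of vehicle and indacaterol at 2 h is argued against as well. Of the 276 genes called for indacaterol at 2 h without replicate 3, 97.8% changed in the same direction in replicate 3, with a median rise of 0.73 against 0.69. This test used only the vehicle and indacaterol arrays of replicate 3 at 2 h, and other exchanges of labels were not tested. A different summarization of the probe sets of replicate 3 (settings not stated), a largely different cell population, another stock of the line or another growth state stays open. These were not tested, because the labels name none of them.

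Among gene lists, outlying arrays were found in 9 of 16 groups for squamous differentiation genes and in 6 for ion transport and mucin genes, in replicate 3 each time. They were found in 2 groups each for YAP targets, ERK outputs and cholesterol synthesis genes (replicate 3), in 2 for ciliated and secretory markers, and in 1 each for cAMP components, cytokines, growth factors, mitotic genes and the unfolded protein and amino acid responses. Chance marks about 1 in 20 groups, and the total was 28 of 304, of which 22 fell on replicate 3. For the PDE4 genes it was 3 of 48 groups. For the 40 genes named by rule it was 37 of 640, or 5.78%.

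The indacaterol effect differed between times for 53 genes by limma's F-test. The interaction was called for 5 list tests with the preset correlation: CREB targets at 2 h, interferon-stimulated genes at 6 and 18 h, leukocyte markers at 6 h and squamous differentiation genes at 18 h. With an estimated correlation 0 of the 5 passed (adjusted p = 0.932, 0.713, 0.987, 0.468 and 0.231), and the squamous call was also lost with the block (0.108) and without replicate 3 (0.76).

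Among 13522 probe sets without a single gene symbol, which the comparisons left out, limma called 14, 41 and 2 for indacaterol at 1, 2 and 6 h, 6 and 1 for GSK at 1 and 2 h, 20, 27 and 10 for both drugs at 1, 2 and 6 h, and 1 for the interaction at 18 h. The greatest rise with both drugs at 6 h was 2.04 ± 0.28 (adjusted p = 1.52e-05), for a probe set with no gene name.

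The 8 arrays of a comparison were split in all 35 ways into 4 and 4, without regard to replicate numbers. For indacaterol at 1, 2 and 6 h 1 of 35 splits, the real one, gave as many calls (42, 237 and 54, highest other 2, 151 and 1). For both drugs at 1, 2, 6 and 18 h 1 of 35 did too (56, 208, 150 and 7, highest other 0, 1, 1 and 1). Same-numbered arrays resemble each other, so the 35 splits are not exchangeable and this share does not exclude chance. The split with 151 calls put indacaterol replicates 1, 2 and 3 with vehicle replicate 3. For indacaterol at 18 h 4 of 35 splits gave as many calls (real 1, highest other 7, with replicates 1 and 3 of both groups against 2 and 4). For GSK at 1 h 4 of 35 did (real 1, highest other 164). A real count of 0 cannot be tested this way, since 35 of 35 splits give as many by construction. This holds for GSK at 2, 6 and 18 h (highest other 81, 0 and 4) and both drugs against indacaterol at 1, 2, 6 and 18 h (highest other 1, 56, 21 and 34). The split with 164 calls exchanged GSK replicate 1 and vehicle replicate 4, and 141 of its genes (86%) were below the median brightness. Splits that call several times the real count point to a structure of the samples, and those with 56, 21 and 34 calls set replicates 1 and 3 against 2 and 4. Of the 8 splits that part all 4 same-numbered pairs, where the numbers pair the samples, the real one alone gave as many calls in each comparison with any call, the others giving at most 2, but 8 splits are too few for a share under 0.05.

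Random regroupings were drawn for the other tests. For the interactions the real count of 0 cannot be tested this way, since 100 of 100 give as many by construction, with up to 140, 390, 49 and 5 calls at 1, 2, 6 and 18 h. These regroupings mix treated and vehicle arrays, so they can also pick up the effect of a drug, and what gave their calls was not tested. For the indacaterol effect over time 2 of 100, the real one included, gave 53 or more, and the other gave 663. For vehicle over time 1 of 100 gave as many as 1315, with a highest other of 365. The draws ignore replicate numbers. Those for the indacaterol effect also mix treated and vehicle arrays, so they cannot tell an effect that changes with time from a constant one. For vehicle only the times were shuffled, and there the real count exceeded every other draw.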

How the results depend on the processing

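The fit with replicate number as a block on replicates 1, 2 and 4 was chosen after the data were seen, and every other alternative was planned. Values per comparison are counts of genes called, in the order 1, 2, 6 and 18 h. No call of a gene named by rule reversed in the alternatives run on its own probe set, while other probe sets of CRISPLD2, CLIC5, CYP2E1, SLC20A2 and ZNHIT2 gave the opposite sign without being called. Of the 69 calls of genes named by rule, 69 held with the replicate block, 67 with trend and robust moderation, 67 with log2(value + 1), 64 with all named probe sets, 63 with quantile normalization, 29 with only the arrays of the comparison, and 38, 47, 46 and 54 without replicate 1, 2, 3 or 4. With all named probe sets each gene kept its lowest adjusted p, so a flat probe set beside a called one could not remove a call there. Of 53 list calls 50 held with the block, 38 with quantile normalization, 13 with fry, and 41, 42, 43 and 46 without replicate 1, 2, 3 or 4.

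The replicate block gave 206, 751, 457 and 7 for indacaterol (42, 237, 54 and 1 without it), 282, 683, 1043 and 80 for both drugs (56, 208, 150 and 7), 1 for the interaction at 1 h, 394 for the indacaterol effect over time and 4415 for vehicle over time. It kept every gene called without it against vehicle. On replicates 1, 2 and 4 the block gave 114, 586, 303 and 2 for indacaterol, 0 and 1 for GSK at 1 and 2 h, 135, 439, 505 and 15 for both drugs, and 252 and 3330 for the F-tests. Where the numbers do not pair the samples (indacaterol at 2 h, same-number r from 0.0802 to 0.826, GSK at 2 h, from -0.0527 to 0.732, both drugs at 1 h, from 0.0804 to 0.857, both drugs against indacaterol at 1 h, from 0.0845 to 0.825, and the interactions at 1 and 2 h), 63 of 64 arrays still correlated best on average with their own number, the exception being vehicle replicate 2 at 18 h. With the block PDE4B and PDE4D passed with both drugs at 1 h (adjusted p = 0.0198 and 0.00239). In these comparisons the block also added list calls: hypoxia-inducible genes with indacaterol at 2 h (adjusted p = 0.01), interferon-stimulated genes with GSK at 2 h (0.0382), with both drugs at 1 h (0.00398) and against indacaterol at 1 h (0.00095), growth factors with both drugs at 1 h (0.00326), and the interactions of CREB targets at 1 h (0.00215) and glucocorticoid-inducible genes at 2 h (0.0317), at 0.533 or more with the block and an estimated correlation. The values given here and beside the results are not a full list of the calls that the block added for named genes.

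With only the arrays of the comparison the counts were 11, 63, 5 and 0 for indacaterol, 0 for GSK at 1 h, 8, 70, 16 and 0 for both drugs, and 1 for both drugs against indacaterol at 2 h; fewer arrays estimate the spread there. Quantile normalization gave 89 and 0 for indacaterol at 6 and 18 h, 0 for GSK at 1 h, 322 and 329 for both drugs at 2 and 6 h, and 87 for the indacaterol effect over time. The indacaterol call at 18 h also fell to 0 with trend and robust moderation, with all named probe sets and with dim genes left out, as did GSK at 1 h with dim genes left out, a filter that removed both genes. The cause was not tested for the other changes.

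Leaving out single arrays or a replicate number gave from 18 to 54, 99 to 276, 22 to 97 and 0 to 4 for indacaterol, 0 to 12, 0 to 1, 0 to 1 and 0 to 1 for GSK, 18 to 87, 94 to 215, 59 to 171 and 0 to 10 for both drugs, 8 to 66 for the indacaterol effect over time and 350 to 1561 for vehicle over time, with fewer arrays in each fit. Of the 7 genes called with both drugs at 18 h, 0 were called without replicate 1 or without replicate 3. With the vehicle arrays split between comparisons the median overlap of indacaterol and both drugs was 16.5, 71.5, 19.5 and 0, and that of indacaterol and GSK at 1 h was 0. Other probe sets gave -0.054 for PDE4B and -0.058 for PDE4D with both drugs at 2 h and -0.13 for PDE4D with indacaterol at 2 h. Flat probe sets beside a called one gave 0.033 and 0.048 for CSGALNACT1 with indacaterol and both drugs at 6 h, -0.048 and -0.066 for KLF7 with indacaterol at 2 h, -0.011 for THAP3 with both drugs at 1 h, and, at a signal of 44.9, 0.0040 to 0.27 for NR4A3. Low signal over background limits NR4A3, FSD2, CYP2E1 and MMP20, whose fold changes depend on the offset. With log2(value + 1) NR4A3 rose by 6.25 and 6.13 with indacaterol and both drugs at 2 h and by 3.96 with both drugs at 6 h, against 5.58, 5.46 and 2.62. MMP20 rose by 2.37 against 0.86 with both drugs at 18 h, FSD2 by 0.76 against 0.57 there and by 0.79 against 0.59 with indacaterol, and CYP2E1 by 0.69 against 0.54 with GSK at 1 h.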

Other observations

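The tests of this part on the later response and on interferon-stimulated genes at 6 h were chosen only after the results were seen.

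Replicate 3 also differed in other fixed lists, with values over its 16 arrays against the other 48. Of 18 NRF2 targets, which serve the response to oxidants, 6 were higher with no overlap: the quinone reductase NQO1, the aldo-keto reductases AKR1C2, AKR1C3 and AKR1B10, ME1 and PIR. Of 22 glucocorticoid-inducible genes FKBP5, SCNN1A, GLUL and TFCP2L1 were higher with no overlap, and the list differed by a median of 0.39. YAP targets differed by -0.39, with the receptor kinase AXL and ASAP1 lower with no overlap, and interferon-stimulated genes by -0.46 with 0 members free of overlap. Among fibroblast markers PDGFRB and THY1 were lower and S100A4 higher. Of the 87 genes at least 4-fold higher there, 49 had 89 other probe sets, of which 76 were higher and 42 higher with no overlap, with a median difference of 1.01 against 2.86 for the probe sets used. The probe sets used were the brightest of their genes and were selected for that difference, so a smaller one in the others is partly built in.

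The 195 genes that rose with indacaterol at 2 h were chosen on those arrays, which inflates the rise at that time. With indacaterol their mean stood above vehicle by 48% of that rise at 1 h, 39% at 6 h and 3.27% at 18 h.

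The mean of these genes was 0.12 higher with both drugs than with indacaterol at 6 h, and a candidate explanation is that GSK prolongs the response. As large a difference was seen in 10 of 35 splits of the 8 arrays (exact two-sided p = 0.286, real 0.118, highest other 0.212) and both drugs were higher in 2 of 4 same-numbered pairs, so the arrays are too few to decide. A single array stays open too, as the lowest difference with 1 array left out was 0.0591, within the SD of 0.129 and 0.162, and the same-numbered difference of replicate 3 was 0.379, without which the mean over the other 3 pairs was 0.0306. An array-wide shift stays open as well: the median over all genes was -0.00318, but the values were scaled between arrays and no split of the 8 arrays gave more than 0.0303. At 18 h the difference was 0.063, with 17 of 35 splits as large (exact two-sided p = 0.486).

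Interferon-stimulated genes lay below vehicle at 6 h in all 3 treatments with the preset correlation, with 0 members called and adjusted p = 0.87, 0.872 and 0.987 for indacaterol, GSK and both drugs with an estimated one. The vehicle arrays at 6 h stood above vehicle at the other times by 0.382, 0.45, 0.361 and 0.346 in replicates 1 to 4, a mean of 0.385, which is consistent with high vehicle arrays at that time. Treated arrays at 6 h differed from treated arrays at the other times by -0.00177 (SE 0.103) over the 3 treatments, with single values from -0.37 to 0.197 for indacaterol, -0.185 to 0.119 for GSK and -0.192 to 0.591 for both drugs, which leaves open whether the treatments lowered these genes from their own level. No biological explanation for the vehicle level at 6 h was tested.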
